A study of Mus musculus with 12 samples.

How the data were processed

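Small RNA sequencing of mouse skin and skin tumours was analysed in 12 libraries. Per the labels, the mice were of the C57Bl6 strain and were either wild type (WT) or homozygous knockouts of TAp63, the isoform of the p53-family transcription factor p63 that carries the N-terminal transactivation domain. Dorsal skin came from untreated mice aged 4 weeks. Cutaneous squamous cell carcinoma (SCC) came from mice older than 35 weeks that had received ultraviolet radiation (UVR) of 2.5 kJ per square metre, 3 times a week. Tissue was flash frozen and total RNA was extracted with the miRVana kit, per the labels' protocols. WT mice gave 3 skin and 2 SCC libraries, and TAp63 knockout mice gave 3 skin and 4 SCC libraries. The source names differ for every sample, but the labels do not state that each sample is a separate mouse. The p-values therefore measure the spread between these samples, which may be partly technical. The labels give no replicate numbers. Replicates are numbered here in accession order, and the numbers pair nothing.

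The authors deposited 1 table of log2 values with 1251 miRNA rows and 12 columns, and each column matched the title of 1 sample. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool and the miRBase release are not given in the sources used here. From the values, the deposited log2 scale was quantile normalized between libraries: the columns have nearly the same set of values, and on the linear scale each sums to between 6065014 and 6065621. The smallest value in every library is the log2 of 10, so lower values had been set to that floor. Of the 1251 rows, 647 were at the floor in all 12 libraries. Read counts and library totals are not kept by such values, so the depth of each library is unknown and no counting interval can be given. The number of miRNAs above the floor, 370 to 545 per library, is the nearest measure of depth. A fold change of a miRNA at the floor in 1 group understates the change. Libraries at the floor have no spread, so the SE and p-value of such a miRNA can be too small. Quantile normalization also fixes the value of each rank, so the most abundant miRNA has the same value in every library.

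The 544 miRNAs above the floor in at least 2 libraries were tested. The 60 miRNAs above it in 1 library were not tested. limma 3.58.1 in R 4.3.3 was fitted to the deposited log2 values with a mean for each of the 4 groups, and with moderated variances that follow a trend with abundance and are robust to outlying miRNAs (8 residual degrees of freedom, median prior degrees of freedom 3.2). Contrasts gave SCC against skin in each genotype, their average, knockout against WT in each tissue, and the interaction, which is the knockout tumour effect minus the WT tumour effect. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and an adjusted p under 0.05 was called. The planned design used a count model, or limma on log2(value + 1) for normalized values. The values are already logged, so they were used as deposited, and the pseudocount of 1 became an alternative. The test, the miRNA lists, the rule for naming miRNAs and the first set of alternatives were chosen before the data were examined.

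Of 21 miRNA lists, 17 had at least 3 tested members and were tested with camera from limma, with a preset correlation of 0.01 between members. Adjustment was over the 17 lists in each comparison, and the test was repeated with an estimated correlation. The lists cover p63-linked miRNAs, miRNA families, miRNAs of squamous tumours and keratinocytes, the Dlk1-Dio3 cluster, and markers of muscle, blood, stroma, endothelium, neural tissue, liver and melanocytes. miR-30c-2-3p and miR-497-5p are in the p63-linked list because the study chose them on these mice, so they are not independent evidence. The same limit holds where miR-30c-2-3p counts in the miR-30 star list, and miR-497-5p in the list of miR-15, miR-16 and miR-497. 1 list member, miR-720, had no row. The text names, for each comparison, up to 8 called miRNAs with the largest log2 fold change in each direction among the upper 40% of tested miRNAs by mean level, every tested member of the p63-linked list, and up to 4 members with the smallest p from each list. Some further members of the fixed lists are also named where a list is described. Other names outside this rule are said to be so.

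The fit was tested on simulated tables made from the real means and residual spreads, with 200 of the 544 miRNAs changed. These simulations were first run after the first fit of the data. In 10 simulations of the averaged tumour effect, 55.6% of 2-fold changes and 83.2% of 4-fold changes were recovered. The same shares were 28.8% and 61.6% for the WT tumour effect, 40.4% and 72.9% for the knockout tumour effect, 39.2% and 67.6% for knockout against WT skin, 33.9% and 67.1% for knockout against WT tumours, and 14.3% and 50.8% for the interaction. With no change simulated, at most 1 miRNA was called. The simulated errors were independent, with the same spread in every group and no quantile step. These tables therefore cannot show how often miRNAs above the floor in only 1 group, or with unequal spread, are called falsely.

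Alternatives changed the pseudocount, normalization, low-value filter, libraries in the fit, fold threshold and library weights. Others left out the 5 most abundant miRNAs, merged rows with identical values, or left out each library in turn. The low-value filters asked for at least 1 library above the floor, or a linear value of 60.7 in 2 libraries. Another, called a mean of at least 100 below, asked for a mean log2 value of at least the log2 of 100. There were 25 tested rows in 12 sets with identical values in every library, mostly copies of 1 mature sequence such as miR-199a-3p and miR-199b-3p. Hairpin positions are from RefSeq for GRCm38.p6, the assembly also called mm10, and their place in genes is from GENCODE M21. Figures were drawn with matplotlib 3.10.9. Every tissue contrast also contrasts age, UVR exposure and 2 series of library names, which coincide with tissue, so these cannot be told apart. TAp63 mRNA was not measured by this assay, so the genotype labels could not be checked from the table.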

Results

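miRNA levels were measured in untreated dorsal skin of WT (n = 3) and TAp63 knockout mice (n = 3), and in UVR-induced SCC of WT (n = 2) and TAp63 knockout mice (n = 4). The study's title concerns miRNAs regulated by TAp63 that suppress this tumour. Values are the authors' quantile-normalized log2 values, with a floor at a linear value of 10. The skin libraries had 390 to 433 miRNAs above the floor in WT and 370 to 465 in knockout mice, and the tumours had 402 to 420 in WT and 432 to 545 in knockout mice. Skin and tumours separated on the first principal component, which held 55.3% of the variance. WT SCC replicate 2 lay nearest to skin, at 8.60 against 14.03 to 18.81 for the other 5 tumours and -19.82 to -12.34 for skin. Correlations across miRNAs were 0.956 to 0.989 between libraries of 1 group and 0.883 to 0.956 between skin and tumour libraries, and no pair of libraries held the same values. miR-10b-5p, named here after its values were seen, was the most abundant miRNA in all 6 skin libraries. miR-21a-5p took that place in 5 of the 6 tumours, and miR-27b-3p in WT SCC replicate 2.

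The first question was how SCC differs from untreated skin. Averaged over the genotypes, tumours had far more of both arms of miR-21a and miR-31, which are known as abundant miRNAs of squamous carcinomas, and of miR-92a-3p, a member of the growth-promoting miR-17 cluster. They had far less of the striated muscle miRNAs miR-206-3p and miR-1a-3p, and of the related miR-100-5p and miR-99a-5p. Both members of the melanocyte list, miR-204-5p and miR-211-5p, were also far lower. Of the 544 miRNAs tested, 111 were higher and 117 lower in SCC. miR-21a-3p rose by 5.57 ± 0.44 (log2, SE), or 47.4-fold (adjusted p = 8.0e-06), and miR-206-3p was 73.8-fold lower, at -6.20 ± 0.43 (adjusted p = 7.8e-06). For each of these 2 miRNAs, the 6 tumours lay outside the range of the 6 skin libraries. Median-ratio scaling, chosen after seeing the data, moved the median change of all tested miRNAs from 0.04 to 0.16.

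Among the upper 40% of tested miRNAs by mean level, the other large increases in log2 units were 4.65 ± 0.44 for miR-5105, 4.58 ± 0.86 for miR-31-3p, 3.95 ± 0.68 for miR-31-5p, 3.52 ± 0.52 for miR-6538, 2.91 ± 0.29 for miR-21a-5p, 2.81 ± 0.30 for miR-92a-3p and 2.67 ± 0.30 for miR-193a-3p, with adjusted p-values between 2.2e-05 and 0.00152. The change of miR-21a-5p is limited from above, since it held the highest rank in 5 tumours. Large decreases at these levels included -4.43 ± 0.44 for miR-1a-3p, -3.94 ± 0.39 for miR-204-5p, -3.14 ± 0.25 for miR-100-5p, -2.98 ± 0.69 for miR-6406, -2.68 ± 0.41 for miR-99a-5p and -2.61 ± 0.41 for miR-133a-3p, with adjusted p-values between 8.0e-06 and 0.00535. miR-211-5p was 8.01-fold lower (adjusted p = 0.00479), with 5 of 6 tumours below all skin libraries. For miR-6406, 3 of 6 tumours lay below all skin libraries.

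In mm10, the miR-21a hairpin lies on chromosome 11 at 86584067 to 86584158 and overlaps an annotated exon of Vmp1 on the same strand. The miR-31 hairpin lies on chromosome 4 at 88910557 to 88910662, in an exon of a long intergenic noncoding RNA. The miR-206 hairpin (chromosome 1, 20679010 to 20679082) and the miR-133b hairpin (chromosome 1, 20682769 to 20682887) overlap exons of 1 noncoding RNA. miR-204 lies in an intron of Trpm3 (chromosome 19, 22750605 to 22750672), and miR-211 in an intron of Trpm1 (chromosome 7, 64205806 to 64205911). Mature miR-1a-3p and miR-133a-3p each come from 2 hairpins, on chromosomes 2 and 18, and their values cannot be assigned to 1 locus. No entry of the reference annotation matched miR-5105.

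**Figure D1:**
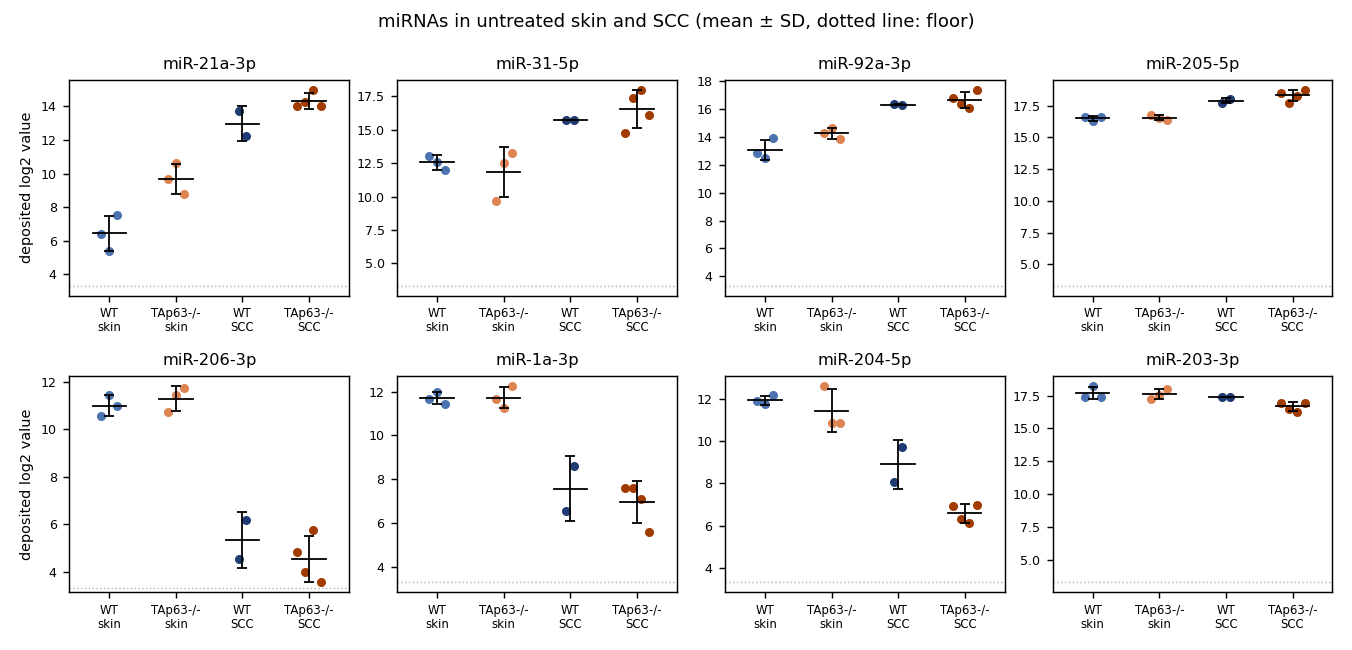
Deposited log2 values of 8 miRNAs in each library (points) of the 4 groups, with the group mean and SD (bars) and the floor at a linear value of 10 (dotted line). miR-21a-3p was 47.4-fold higher and miR-206-3p 73.8-fold lower in SCC than in skin, averaged over genotypes.

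In the averaged comparison, camera called 5 of the 17 lists with the preset correlation of 0.01, and none with an estimated correlation. The estimated correlations in these lists ran from 0.098 (squamous tumour) to 0.738 (muscle). A shift of any of these lists as a group is therefore not established, and the calls of single members are given beside each. Of 11 tested members of the miR-17 cluster and its paralogs, 10 rose and none fell, including miR-92a-3p, miR-18a-5p (2.59 ± 0.42), miR-19a-3p (2.18 ± 0.41) and miR-20a-5p (1.69 ± 0.23). Among the 10, miR-20b-5p was above the floor only in the WT tumours, with a tumour effect of 1.36 in WT and 0 in knockout mice. Its averaged call therefore does not show a rise in both genotypes. Adjusted over the list alone, 10 also rose. The list's adjusted p was 5.3e-05 with camera, and adjusted p = 0.173 with an estimated correlation. Of 7 squamous tumour miRNAs, 5 rose and none fell, both over all tested and adjusted over the list alone. They were the arms of miR-21a and miR-31 and the hypoxia-induced miR-210-3p (1.48 ± 0.40), and the list had an adjusted p of 0.00335, with adjusted p = 0.188 with an estimated correlation.

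Of 34 tested miRNAs of the imprinted Dlk1-Dio3 cluster, 19 fell and none rose, again with the same counts adjusted over the list alone. miR-299a-5p fell by 3.21 ± 0.38, miR-379-5p by 2.39 ± 0.27 and miR-154-5p by 1.80 ± 0.30. The list's adjusted p was 0.000144, with adjusted p = 0.521 with an estimated correlation. The skin donors were younger than the tumour donors, so this decrease and the age difference go together. All 6 tested star arms of the miR-30 family fell, also adjusted over the list alone, from miR-30a-3p (-1.86 ± 0.23) to miR-30d-3p (-0.67 ± 0.23). Their list had an adjusted p of 0.00876 with camera and adjusted p = 0.521 with an estimated correlation. These 6 include miR-30c-2-3p, which the study chose on these mice, so the count and the list test are not fully independent evidence. Guide arms of the family did not move together: miR-30a-5p fell by 1.22 ± 0.19, and miR-30e-5p rose by 0.76 ± 0.16. The other 3 of the 5 were not called, over all tested or adjusted over the list alone (list adjusted p = 0.992).

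Markers of other cell types differed as well. Of 5 striated muscle miRNAs, 4 fell, over all tested and adjusted over the list alone, and their decreases were unequal, at 6.20 for miR-206-3p, 4.43 for miR-1a-3p, 2.61 for miR-133a-3p and 2.59 for miR-133b-3p on the log2 scale. The fifth, miR-499-5p, was 1.20 ± 0.55 (adjusted p = 0.110). The list's adjusted p was 0.00876, with adjusted p = 0.521 with an estimated correlation. The red cell miRNAs miR-451a (2.61 ± 0.47) and miR-144-3p (2.14 ± 0.41) rose, and the other 2 of 4 erythroid members were not called, with the same counts adjusted over the list alone (list adjusted p = 0.280). Of 7 leukocyte miRNAs, miR-142-3p (1.19 ± 0.30) and the myeloid miR-223-3p (1.20 ± 0.33) rose, while miR-146a-5p (-2.50 ± 0.25) and miR-146b-5p (-0.91 ± 0.29) fell, and both counts were the same adjusted over the list alone. Neither miR-223-3p (adjusted p = 0.0793) nor miR-146b-5p (-0.60, adjusted p = 0.146) was called without WT SCC replicate 1. The call of miR-146b-5p also ended without WT skin replicate 2 (0.0509) or 3 (0.0504) or knockout skin replicate 3 (0.0616). The leukocyte list itself was not called (adjusted p = 0.992; median 0.09, mean -0.12). Of 7 stromal miRNAs, miR-199b-5p (-1.55 ± 0.23) and miR-199a-5p (-1.14 ± 0.27) fell, and 2 also fell adjusted over the list alone (list adjusted p = 0.176).

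**Figure D2:**
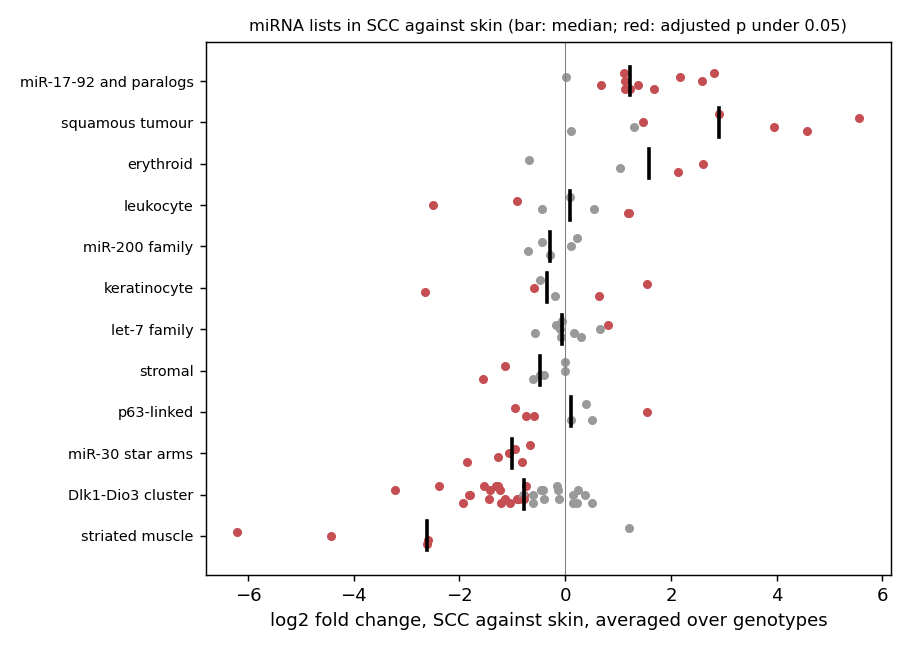
Log2 fold change of each tested member of 12 miRNA lists in SCC against skin, averaged over genotypes, with called members in red, others in grey and the list's median as a bar. 10 of 11 members of the miR-17 cluster and its paralogs and 4 of 5 muscle members were called, in opposite directions. Among the called miR-17 paralogs, miR-20b-5p was at the floor outside the WT tumours.

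The keratinocyte list had 6 tested members and no common direction (adjusted p = 0.992). miR-205-5p, a keratinocyte miRNA linked to p63, rose by 1.55 ± 0.19 (2.92-fold, adjusted p = 1.1e-04), and all 6 tumours exceeded the 6 skin libraries. miR-27b-3p rose by 0.65 ± 0.19, but without WT SCC replicate 2 it changed by 0.34 (adjusted p = 0.0509). miR-184-3p fell by 2.66 ± 0.54. miR-203-3p, which promotes keratinocyte differentiation, fell by 0.60 ± 0.21 (adjusted p = 0.0416), but median-ratio scaling gave -0.48 (adjusted p = 0.0952), library quality weights -0.64 (0.0709) and leaving out the 5 most abundant miRNAs -0.47 (0.0958). This call also ended without WT skin replicate 2, knockout skin replicate 2 or 3, either WT SCC library, or knockout SCC replicate 2 or 3, with adjusted p-values of 0.0612 to 0.106. Over the list alone, 2 rose and 2 fell. None of the 5 miR-200 family members, which maintain epithelial identity, was called, also adjusted over the list alone (list adjusted p = 0.992).

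The p63-linked list had 7 tested members, of which 1 rose and 3 fell, with the same counts adjusted over the list alone. The list was not called (adjusted p = 0.992, direction down, with a median of 0.11 and a mean of 0.04). Besides miR-205-5p and miR-203-3p, miR-497-5p fell by 0.74 ± 0.19 (1.67-fold, adjusted p = 0.00997) and miR-30c-2-3p by 0.96 ± 0.33 (1.94-fold, adjusted p = 0.0387). The study chose these last 2 on these mice, so neither is independent evidence. Leaving out WT SCC replicate 1 gave an adjusted p of 0.0533 for miR-497-5p and 0.128 for miR-30c-2-3p, and for miR-30c-2-3p median-ratio scaling gave 0.0597 and library quality weights 0.128. The call of miR-30c-2-3p also ended without WT skin replicate 1 or 3, knockout skin replicate 1 or 2, WT SCC replicate 2, or knockout SCC replicate 2 or 3 (adjusted p 0.0557 to 0.0922). The changes of miR-34c-5p (0.51 ± 0.41), miR-34a-5p (0.39 ± 0.23) and miR-130b-3p (0.11 ± 0.29) were not called. For miR-34c-5p the change was -0.09 without WT SCC replicate 1, and 1.11 without WT SCC replicate 2 (adjusted p = 0.0219). The miR-497 hairpin lies on chromosome 11 at 70234717 to 70234800, outside annotated host genes, and the miR-30c-2 hairpin on chromosome 1 at 23291701 to 23291784, in an exon of a noncoding RNA.

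In WT mice alone, 48 miRNAs were higher and 51 lower in SCC (n = 2) than in skin (n = 3). miR-21a-3p rose most, from 6.45 ± 1.05 (SD, n = 3) to 12.96 ± 1.05 (SD, n = 2), a change of 6.51 ± 0.68 (SE, adjusted p = 2.6e-04). miR-5105 (4.49), miR-6538 (4.10), miR-92a-3p (3.24), miR-21a-5p (2.91), miR-193a-3p (2.81), miR-138-5p (2.72) and miR-18a-5p (2.50) were the other leading increases, in log2 units, among called miRNAs in the upper 40% by mean level. miR-31-3p (3.71) and miR-31-5p (3.17) were not called in WT mice. Among called miRNAs in the upper 40%, miR-206-3p fell by 5.65, miR-1a-3p by 4.12, miR-6406 by 3.87, miR-99a-5p by 3.07, miR-204-5p by 3.03, miR-100-5p by 2.96, miR-146a-5p by 2.49 and miR-133a-3p by 2.42. With the 2 WT groups fitted alone, which called 62 miRNAs in all, the calls ended for miR-1a-3p (adjusted p = 0.0634), miR-204-5p (0.0678), miR-18a-5p (0.0820), miR-99a-5p (0.108), miR-6406 (0.133) and miR-133a-3p (0.175).

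Of the p63-linked miRNAs, miR-205-5p rose in WT tumours by 1.35 ± 0.29 (adjusted p = 0.00846). Not called were miR-34c-5p (1.48 ± 0.62), miR-34a-5p (0.47 ± 0.35), miR-130b-3p (0.24 ± 0.44), miR-203-3p (-0.27 ± 0.33), miR-30c-2-3p (-0.41 ± 0.51) and miR-497-5p (-0.71 ± 0.30). Adjusted over the list alone, 1 rose. The lists called were the miR-17 cluster with 5 of 11 members higher (8 adjusted over the list alone; adjusted p = 2.9e-05, and adjusted p = 0.148 with an estimated correlation), squamous tumour with 2 of 7 higher (5 adjusted over the list alone; 0.00247, and adjusted p = 0.148 with an estimated correlation), and muscle with 4 of 5 lower in both counts (0.00413, and adjusted p = 0.625 with an estimated correlation). The Dlk1-Dio3 list had 6 of 34 lower in both counts (0.00413, and adjusted p = 0.625 with an estimated correlation), and the miR-30 star list 3 of 6 lower (4 adjusted over the list alone; 0.0150, and adjusted p = 0.625 with an estimated correlation). The WT count depends on single libraries: it was 32 without WT SCC replicate 1, 61 without WT skin replicate 2 and 65 without WT skin replicate 1, against 99 with all. Without WT SCC replicate 1, the adjusted p was 0.0653 for miR-6538, 0.311 for miR-138-5p, 0.192 for miR-18a-5p, 0.314 for miR-6406 (then -2.23), 0.104 for miR-99a-5p, 0.0927 for miR-204-5p and 0.258 for miR-133a-3p (then -1.20). Without WT SCC replicate 2, miR-133a-3p was at -3.64. Both miR-34c-5p (2.69, adjusted p = 0.00801) and miR-497-5p (-1.13, adjusted p = 0.0286) were called without WT SCC replicate 2, but without WT SCC replicate 1 they were at 0.28 (adjusted p = 0.915) and -0.28 (adjusted p = 0.729). Leaving out any 1 WT skin library ended the calls of miR-138-5p, miR-6406 and miR-133a-3p (adjusted p 0.0531 to 0.117), and WT skin replicate 3 those of miR-18a-5p (0.0718) and the miR-30 star list (0.0529). For miR-138-5p, leaving out any knockout skin library (0.0660 to 0.0713), WT SCC replicate 2 (0.0778) or knockout SCC replicate 1 or 3 (0.0586 and 0.0542) also ended the call, as did a pseudocount of 10 (0.0509), quantile normalization repeated on the tested miRNAs (0.0523), no filter beyond 1 library above the floor (0.0716) and leaving out the 5 most abundant miRNAs (0.0530).

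In TAp63 knockout mice, 87 miRNAs were higher and 99 lower in SCC (n = 4) than in skin (n = 3). Among the upper 40% of tested miRNAs by mean level, the largest increases, in log2 units, were of miR-31-3p (5.44 ± 1.11), miR-5105 (4.82 ± 0.56), miR-31-5p (4.73 ± 0.87) and miR-21a-3p (4.62 ± 0.57), followed by miR-6538 (2.93), miR-21a-5p (2.91), miR-6240 (2.80) and miR-451a (2.76). The largest decreases at these levels were of miR-206-3p (-6.76 ± 0.55), miR-204-5p (-4.84 ± 0.50), miR-1a-3p (-4.74 ± 0.56) and miR-100-5p (-3.32 ± 0.32), followed by miR-338-3p (-2.83), miR-133b-3p (-2.82), miR-133a-3p (-2.80) and miR-379-5p (-2.67). The adjusted p-values of these 16 miRNAs lay between 4.2e-05 and 0.00546.

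Of the p63-linked miRNAs, miR-205-5p rose in knockout tumours by 1.74 ± 0.24 (adjusted p = 4.5e-04). miR-30c-2-3p was 2.84-fold lower (adjusted p = 0.0185), and miR-203-3p fell by 0.92 ± 0.27 (adjusted p = 0.0224) and miR-497-5p by 0.78 ± 0.25 (adjusted p = 0.0324). Without knockout skin replicate 2, these 3 adjusted p-values were 0.0630, 0.0553 and 0.0541. Without knockout skin replicate 1, miR-30c-2-3p (0.0897), miR-497-5p (0.133) and the miR-30 star list (0.0593) were not called. The call of miR-203-3p also ended without knockout skin replicate 3 (0.101) or knockout SCC replicate 3 (0.0551), and that of miR-497-5p without knockout SCC replicate 1 (0.0598). miR-34c-5p (-0.47 ± 0.52), miR-34a-5p (0.32 ± 0.29) and miR-130b-3p (-0.02 ± 0.37) were not called, and the counts adjusted over the list alone were again 1 higher and 3 lower. The same 5 lists were called as in WT mice. The miR-17 cluster had 8 of 11 members higher (9 adjusted over the list alone; adjusted p = 3.1e-04, and adjusted p = 0.289 with an estimated correlation), squamous tumour 5 of 7 higher in both counts (0.0109, and adjusted p = 0.289 with an estimated correlation), and the Dlk1-Dio3 cluster 19 of 34 lower in both counts, with 1 higher adjusted over the list alone (4.8e-05, and adjusted p = 0.405 with an estimated correlation). Muscle had 4 of 5 lower and 1, miR-499-5p, higher in both counts (0.0112, and adjusted p = 0.565 with an estimated correlation). The miR-30 star list had 4 of 6 lower in both counts (0.0215, and adjusted p = 0.565 with an estimated correlation).

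The tumour effects of the 2 genotypes share no library and could be compared directly. Across the 544 miRNAs, which are not independent replicates, their Pearson correlation was 0.811 and their Spearman correlation 0.757. 36 miRNAs were higher in both, where independent lists would share 7.7, and 41 were lower in both, where 9.3 would be shared. Both sets of calls use the same variance for each miRNA, from 1 fit, so they are not independent and these expected numbers are only a rough guide. None was called in opposite directions, and 96 of the 99 WT calls had the same sign in knockout mice.

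**Figure D3:**
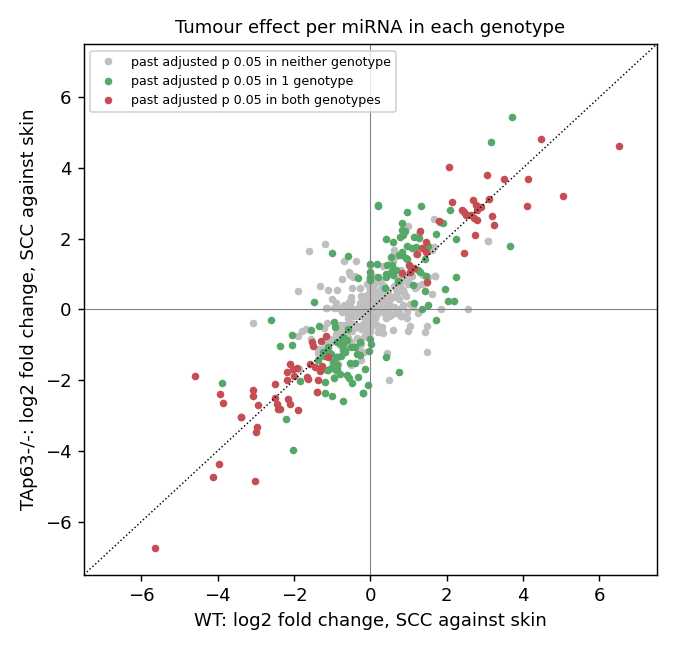
Log2 fold change of SCC against skin for each of 544 miRNAs in WT (x axis) and TAp63 knockout mice (y axis), coloured by whether it was called in both, 1 or neither genotype. The dotted line marks equal effects, and the correlation across miRNAs was 0.811.

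The next question was what loss of TAp63 changes in untreated skin. No single miRNA was called between knockout (n = 3) and WT skin (n = 3) by limma, and 31 had an unadjusted p under 0.05, where 27.2 would by chance. The smallest adjusted p belonged to miR-21a-3p, which was 3.24 ± 0.61 higher in knockout skin (adjusted p = 0.121), at 9.69 ± 0.90 against 6.45 ± 1.05 (SD). With library quality weights, chosen after seeing the data, 20 miRNAs were called higher and 2 lower, among them miR-21a-3p (3.80, adjusted p = 0.00381), miR-127-5p (2.32, adjusted p = 0.00381) and miR-381-3p (1.86, adjusted p = 0.00680). Leaving out knockout skin replicate 3 gave 2 calls, with miR-21a-3p at an adjusted p of 0.0497.

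Of the 34 Dlk1-Dio3 miRNAs, 32 had a positive and 1 a negative log2 change in knockout against WT skin, with a median of 0.40. Camera with its preset correlation called the list higher (adjusted p = 8.7e-08). With the estimated correlation of 0.188 it was not called (adjusted p = 0.308). These members share 1 cluster, so their signs are not independent, and an increase of the group is not established. No member was called with equally weighted libraries, also adjusted over the list alone. Its member miR-381-3p, called with quality weights, differed by 1.79 ± 0.45 (adjusted p = 0.252), and miR-329-3p by 1.65 ± 0.55. miR-127-5p, which is encoded in the same cluster but lay outside the list and was chosen after its values were seen, was also called with those weights and differed by 2.14 ± 0.49 (adjusted p = 0.252). The 5 miR-34 family arms, which respond to p53, all had positive log2 changes too (median 0.88). Camera called this list higher with the preset correlation (adjusted p = 0.00245) but not with the estimated one (adjusted p = 0.308). No member of it was called, also adjusted over the list alone. miR-21a-3p was called when adjusted over the squamous tumour list alone, and that list was not (adjusted p = 0.953). The p63-linked list was not called (adjusted p = 0.953), and no member passed adjusted over the list alone. Its members differed by 0.79 ± 0.46 for miR-30c-2-3p, 0.29 ± 0.31 for miR-34a-5p, 0.05 ± 0.26 for miR-205-5p, 0.03 ± 0.39 for miR-130b-3p, -0.08 ± 0.29 for miR-203-3p and -0.27 ± 0.27 for miR-497-5p. miR-34c-5p was at 11.52 ± 0.17 in knockout and 10.52 ± 0.64 in WT skin (SD).

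Between knockout (n = 4) and WT tumours (n = 2), 1 miRNA was called and 46 had an unadjusted p under 0.05. miR-20b-5p, a miR-17 cluster paralog chosen after its values were seen because it was the single call, was lower in knockout tumours by 1.36 ± 0.19 (adjusted p = 0.0107). It lay at 4.68 ± 0.51 (SD, n = 2) in WT tumours and at the floor in the other 10 libraries, so the difference concerns levels close to the floor. Values at the floor have no spread, so the SE of 0.19 and the adjusted p understate the uncertainty, and the call is weak evidence. A pseudocount of 10 gave -0.84. With the 2 tumour groups fitted alone, the adjusted p was 0.664, and the filters on per-million level and on mean level remove this miRNA. Leaving out WT SCC replicate 2 gave 13 calls, all lower in knockout tumours, and the count was 3 without knockout SCC replicate 3 and 2 without WT SCC replicate 1 or knockout SCC replicate 2. The miR-20b hairpin lies on chromosome X at 52742113 to 52742192, outside annotated host genes. No list was called (smallest adjusted p = 0.160), and no p63-linked member was, also adjusted over the list alone. The p63-linked differences were -0.96 ± 0.59 for miR-34c-5p, -0.74 ± 0.31 for miR-203-3p, -0.35 ± 0.28 for miR-497-5p, -0.30 ± 0.49 for miR-30c-2-3p, -0.23 ± 0.42 for miR-130b-3p, 0.15 ± 0.33 for miR-34a-5p and 0.43 ± 0.28 for miR-205-5p. Without WT SCC replicate 1, miR-34c-5p was at 0.25, and without WT SCC replicate 2, miR-497-5p was at 0.0745.

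**Figure D4:**
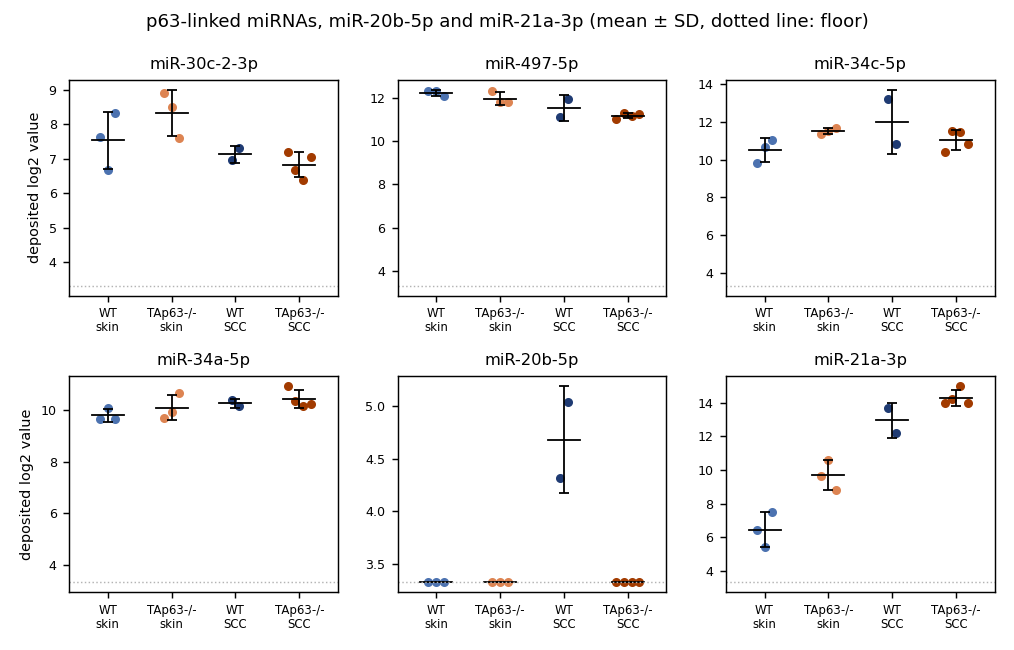
Deposited log2 values of 6 miRNAs in each library (points), with the group mean and SD (bars) and the floor at a linear value of 10 (dotted line). miR-20b-5p was above the floor in the 2 WT tumours, and miR-34c-5p was highest in WT SCC replicate 1.

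Whether the tumour effect depends on genotype was tested by the interaction. No miRNA was called by limma, and 41 had an unadjusted p under 0.05. The miR-34 family was the 1 list called (5 members, all negative, median -1.96, adjusted p = 0.00154, and adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone, 4 of its 5 members were lower. For 4 of the 5 arms the tumour effect was positive in WT and negative in knockout mice, as for miR-34c-5p at 1.48 ± 0.62 and -0.47 ± 0.52. Without WT SCC replicate 1, the list's adjusted p was 0.0986 and its median -1.15. The hairpins of miR-34c (51103034 to 51103110) and miR-34b (51103562 to 51103645) neighbour each other on chromosome 9, within an intron of Btg4 on the other strand, and miR-34a is encoded on chromosome 4. For the p63-linked list (adjusted p = 0.281, no member called, also adjusted over the list alone), the interaction was -1.96 ± 0.81 for miR-34c-5p, -1.09 ± 0.67 for miR-30c-2-3p, -0.65 ± 0.42 for miR-203-3p, -0.26 ± 0.57 for miR-130b-3p, -0.14 ± 0.46 for miR-34a-5p, -0.08 ± 0.39 for miR-497-5p and 0.38 ± 0.38 for miR-205-5p. Calls of miR-30c-2-3p and miR-203-3p in knockout but not WT tumours are therefore not shown to differ between genotypes. A fit without WT SCC replicate 2 called 11 miRNAs, all lower, among them miR-34c-3p (-3.88, adjusted p = 0.0233) and miR-34c-5p (-3.16, adjusted p = 0.0358), which were at -1.50 and -0.75 without WT SCC replicate 1 and not called. Without WT SCC replicate 1, miR-20b-5p was at -1.72. It lay at the floor in every library outside the WT tumours. With 1 WT tumour left out, its values have no spread within any group, so a call of it in such a fit is not evidence. Without knockout SCC replicate 2, 1 miRNA was called.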

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

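The tests of the muscle, miR-34 and miR-200 patterns were chosen after their results were seen, and the counts over other groupings of the libraries were planned before.

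The count of 228 miRNAs that differed between SCC and skin, averaged over genotypes, was set against other splits of the libraries within each genotype. Of 100 splits drawn from 350, 1 gave as many calls, which was the real split, and the highest count among the others was 1. A chance split of these libraries is therefore unlikely to give this count. For the knockout tumour effect, 1 of all 35 splits gave 186 calls, again the real one, and the highest other count was 75. Chance is unlikely here too, but 35 splits cannot give a share under 1 in 35. Between knockout and WT skin all 10 splits gave 0 calls, as the real one did, with 0 as the highest other value. These 10 splits are too few to give a share under 0.05.

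Of the 5 tested striated muscle miRNAs, miR-499-5p did not fall. Its tumour effect was 0.41 in WT mice, not called, and 1.99 in knockout mice, called higher. The other 4 fell in tumours by unequal amounts, most of all miR-206-3p and miR-1a-3p. If all came from muscle, a lower share of the same muscle would keep the ratio of miR-1a-3p to miR-133a-3p and miR-133b-3p, but its mean log2 value was -1.63 ± 0.24 (SD, n = 6) in skin and -3.50 ± 0.40 (SD, n = 6) in SCC. The difference of -1.86, which restates the unequal decreases, exceeds the spread between libraries and argues against that explanation as the whole cause on the deposited scale. Median-ratio scaling moves every miRNA of a library alike (median change of the 4 members -3.40, against -3.52 as deposited), so it cannot test the authors' quantile normalization, which stays open. Other sources of these miRNAs, a different type of muscle, age and UVR also stay open and untested.

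The miR-34 list holds miR-34a-5p and the arms of miR-34b and miR-34c, whose hairpins neighbour each other. The tumour effect of miR-34a-5p, encoded on another chromosome, was 0.47 in WT and 0.32 in knockout mice. The list as a whole had a lower tumour effect in knockout than in WT mice by the list test of the interaction (adjusted p = 0.001536), a call lost with an estimated correlation (adjusted p = 0.587). The adjusted p was 0.0986 without WT SCC replicate 1, while leaving out any other single library gave at most 0.0150, so the call depends on that tumour. The median was still -1.15 without it, against -1.96 with all libraries. Between knockout and WT skin the list's median was 0.88 (adjusted p = 0.00245 with camera), a call lost with an estimated correlation (adjusted p = 0.308). That tumour cannot cause the skin values, so whether it accounts for the whole interaction stays open. Median-ratio scaling (0.00270) moves every miRNA of a library alike and so cannot test the authors' normalization, which stays open. Loss of TAp63 stays open as a biological explanation, and 2 WT tumours cannot separate it from the state of 1 of them.

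Knockout SCC replicate 2 was low in 2 of the 5 miR-200 family members by the outlier measure: the gap of the lowest value to the next, divided by the range, was 0.8378 for miR-200a-3p (10.24 against 13.01 to 13.55) and 0.8366 for miR-429-3p (10.35 against 12.82 to 13.30). Of 67 miRNAs tested this way in the 4 knockout tumours, 4 exceeded the limit, where chance gives about 1 in 20, or 3.35, so these low values may be due to chance, while in the same library the myeloid miR-223-3p was highest (13.305 against 12.065 for the next) and miR-138-5p lowest (8.736 against 11.536) without exceeding the limit. The keratinocyte miRNAs miR-205-5p and miR-203-3p had a mean shortfall of 0.49 (log2), 0.161 times the 3.03 of the miR-200 members. This argues against a lower share of epithelial cells as the whole cause on the deposited scale. miR-205-5p still lay below the other 3 tumours (17.72 against 18.21 to 18.75), while miR-203-3p lay within their range. A lower share as part of the cause therefore stays open. All 5 miR-200 members, from loci on chromosomes 4 and 6, lay below the other 3 tumours, which argues against loss of 1 locus. A change of the tumour cells that lowers both loci, as in a shift away from epithelial identity, stays open as an untested hypothesis beside chance.

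By the same measure, miR-142-3p was low in knockout SCC replicate 3 (10.48 against 11.95 for the nearest, ratio 0.8436). miR-6406 was low in knockout SCC replicate 4 (5.22 against 7.32, ratio 0.8509). Among the untested miRNAs, 50 were above the floor in 1 tumour library and in no skin library, against 10 in 1 skin library alone. Knockout SCC replicate 3, which had the most miRNAs above the floor, held 33 of the 50.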

How the results depend on the processing

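Median-ratio scaling, library quality weights, the pseudocount of 1, the mean filter, the filter on the share of the library total and the merging of identical miRNAs were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the labels give no replicate numbers, the numbers used here follow accession order, and skin and tumours were taken separately. DESeq2, edgeR's normalizations and voom were not run because they need counts, a scaling by library totals because the totals are already equal, and a merging of repeated names because there were none. Leaving out 1 WT tumour assumes that the other varies like the remaining groups. Depth is unknown, so no limit from it can be given.

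For the named miRNAs, 1184 of 1231 values under alternatives kept direction and call in the averaged comparison, 795 of 879 in WT, 1159 of 1239 in knockout mice, 294 of 306 between skins, 251 of 257 between tumours and 235 of 246 in the interaction. The WT count was 62 with only the groups compared, and 32 to 118 without single libraries (lowest without WT SCC replicate 1, highest without WT SCC replicate 2). With a mean of at least 100, which left 260 miRNAs to test, the knockout count was 122 and the averaged count 143. Between skins, the count was 22 with library quality weights and 0 to 2 without single libraries. Between tumours it was 0 by limma with the filter on the share of the library total (373 tested), with a mean of at least 100 and with only the groups compared, and 1 to 13 without single libraries, where 46 had an unadjusted p under 0.05 with all. In the interaction it was 0 to 11 without single libraries. The number of lists called by camera was 0 with an estimated correlation in every comparison, against 5 in each tumour comparison, 2 between skins and 1 in the interaction. Without single libraries it was 0 to 1 between tumours and 0 to 2 in the interaction. Apart from fewer miRNAs tested under the filters and fewer libraries, the cause was not tested.

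No reversed value belonged to a called miRNA. With the 5 most abundant miRNAs left out, miR-203-3p was 0.0573 between skins, and miR-205-5p was -0.0727 between tumours and -0.11 in the interaction. Median-ratio scaling gave 0.0716 for miR-130b-3p in knockout mice, and quality weights 0.0736 for miR-497-5p in the interaction. Without single libraries, miR-130b-3p ranged from -0.0254 to 0.50 in WT, -0.27 to 0.20 in knockout mice, -0.0233 to 0.24 averaged, -0.14 to 0.23 between skins, -0.50 to 0.0303 between tumours and -0.53 to 0.0042 in the interaction. Likewise, miR-34c-5p ranged from -0.0942 to 1.11 averaged and -2.16 to 0.25 between tumours, and miR-34a-5p from -0.0213 to 0.27 between tumours and -0.34 to 0.13 in the interaction. Between skins, miR-203-3p ranged from -0.29 to 0.19 and miR-205-5p from -0.0627 to 0.14. miR-497-5p ranged from -0.77 to 0.0745 between tumours and -0.50 to 0.35 in the interaction.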

Other observations

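No test in this part was chosen after its result was seen, and the lists below were fixed in advance. In the averaged comparison of SCC with skin, of 9 let-7 family members, which repress growth-promoting mRNAs, 1 rose, miR-98-5p by 0.80, and the list was not called (adjusted p = 0.933, direction up, median -0.06, mean 0.10). None of the 3 miR-29 members was called by limma (list adjusted p = 0.992, direction down, median 0.20, mean -0.06), and none of the 5 miR-34 members was (list adjusted p = 0.933). Of 6 members of the family of miR-15, miR-16 and miR-497, miR-15b-5p rose by 0.89, and miR-195a-5p fell by 1.42, as miR-497-5p did (list adjusted p = 0.992). The call of miR-15b-5p ended without WT SCC replicate 1 (adjusted p = 0.0645). Adjusted over the list alone, these counts were the same.

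Of 3 neural miRNAs, miR-9-5p fell by 1.72 and miR-128-3p by 1.23, while miR-219-5p rose by 0.90 (0.57 with a pseudocount of 10; list adjusted p = 0.786), with the same counts adjusted over the list alone. The call of miR-219-5p ended without WT skin replicate 1 or 3, any knockout skin library, either WT SCC library or knockout SCC replicate 4 (adjusted p 0.0509 to 0.118). Both members of the melanocyte list, miR-204-5p and miR-211-5p, fell. Whether fewer melanocytes or a change in other cells lowered them was not tested. Of the endothelial pair, miR-126-5p rose by 0.50 (adjusted p = 0.0324), but not without WT skin replicate 2 or 3, any knockout skin library, WT SCC replicate 2 or knockout SCC replicate 3 (0.0504 to 0.107), and miR-126-3p was not called (0.27, adjusted p = 0.190). miR-675-5p, processed from the imprinted H19 transcript, was not called (0.25, adjusted p = 0.683). The liver miRNA miR-122-5p was above the floor in fewer than 2 libraries and was not tested.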
